A study of Mus musculus with 3 samples.

How the data were processed

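Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) enriches genomic DNA fragments with an antibody against 5-methylcytosine (5mC). Per the labels, the DNA came from cardiomyocytes isolated from male C57Bl6/J mice aged 8 weeks, and antibody and library work were done by a sequencing service. The 3 samples are a Sham library, a library from TAC cardiomyocytes (pressure overload of 1 week, per the series title) and an Input library without antibody. Each group has 1 library. Whether a library pooled several animals is not given in the sources used here. The Input library entered the authors' peak calling, per the file headers, and was otherwise not analysed here.

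Reads were processed on mouse build mm10 with BWA 0.7.4-r385, Picard and HOMER 4.5, per the submitters' processing notes. Peaks were called by HOMER in its mode for broad regions, separately in each library against a shared input, per the file headers. Both headers give a peak size of 500 bp, a minimum distance of 1000 bp, an effective genome of 2000000000 bp, and a requirement of at least 4-fold over input with a Poisson p of 0.0001. Total tags were 12585289 in Sham and 14658177 in TAC, and the tag threshold was 11 in Sham and 12 in TAC, per the file headers. Scaled to 10000000 tags these thresholds are 8.74 and 8.19, so the TAC threshold was the lower of the pair. Filtering against input removed 2043 putative Sham peaks and 2297 putative TAC peaks, per the file headers, and a filter on clonal tags removed 206 and 210. The score column that the authors deposited holds the value 1 for every peak, so it ranks no peaks. The deposited lists give start and end of each peak on mm10 and no signal per peak.

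The order of peaks within each deposited list carries information, which was found after the data were examined. Each list runs through 352 blocks in Sham and 414 blocks in TAC, and within a block peaks are sorted by position. With 1 tag fewer per block and 8 tags in the last block, the block values add up to 99.3% of the tags in peaks that the Sham file header gives, and to 99.3% in TAC. With 9 tags in the last block the sums are 103% for both libraries, and with 7 they are 95.7% and 96.2%. The block value is called the inferred tag number below. This reading is not stated in the sources used here, and it is not free of conflict: it puts 4420 Sham peaks (3.25%) below the tag threshold of 11 in the Sham file header and 5267 TAC peaks (3.25%) below that of 12. It also understates the strongest peaks. It was used to rank and filter peaks within a list and, scaled by the total tags, to set nearly equal thresholds for both libraries (8.74 tags per 10000000 in Sham and 8.87 in TAC) and to estimate counting error. All results at a nearly equal depth-scaled threshold rest on it.

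Peaks were taken as shared when they overlapped a peak of the other library by at least 1 bp. The overlap expected without a shared position was taken from 100 circular shifts of each list along its chromosome, and from 100 shifts by 20 to 200 kb. Genes were those of the RefSeq annotation of GRCm38, the assembly that mm10 names. A peak was assigned to a gene by its midpoint. The annotation used gives gene starts and ends without strand or transcripts, and no genome sequence was used. Promoters, exons, untranslated regions and CpG islands, which had been planned, were therefore not analysed here. In place of promoters, a gene end was counted as covered when a peak overlapped the 1000 bp on either side of the annotated start or end of the gene, and the 5' and 3' ends could not be told apart.

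The 19 gene lists, the comparisons and the rule for named genes were chosen before the data were examined. Named genes were the 12 protein-coding genes with the highest lower bound, and the 12 with the lowest upper bound, of the exact 95% binomial interval of the TAC share of their peaks. The rule adds, for each library, the 10 genes with the widest peak at a gene end covered in that library alone, 13 genes fixed by name, and, from the muscle, calcium, transcription factor and DNA methylation lists, genes covered at an end in 1 library. Imprinted and germline genes covered at an end in both libraries served as reference loci. Other examples from the lists were chosen after their values were seen. Gene-density classes, chromosome ratios and gene families were also chosen after the data were examined.

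For each list the TAC to Sham ratio of peaks summed over its genes was set among 10000 random lists of the same size, matched on deciles of peak number per gene. Lists of covered gene ends were set among random lists matched on deciles of gene length. Percentiles describe these 2 libraries. With 1 library per group there is no spread between replicates, no test of Sham against TAC was run, and no p-value is given. Intervals are exact (Clopper-Pearson for shares, and from the binomial share for ratios of counts) at 95% and cover counting error only. Neighbouring peaks are not independent, so the intervals are too narrow even for that.

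Functions were tested on simulated data. In a copy of the Sham list in which 59.9% of peaks had been kept, the overlap step returned 59.9%. Among 1645 genes with at least 10 Sham peaks, of which 200 were given a 4-fold change in the odds on either side of an even share, the interval set 94.0% of the changed genes apart and 3.04% of the others. Of 100 simulated lists of unchanged genes, 100 lay within the central 95% of random lists when the pool held the changed genes, and 98 when it did not. All 100 lists of changed genes, in which every member was changed in the same direction, lay above it. Lists with only some changed members were not simulated.

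Alternatives covered the overlap rule, the number of peaks, chromosomes, gene ends, gene borders and merging of near peaks. Filters on the inferred tag number, window sizes and matching of lists on gene density were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.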

Results

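5mC-enriched regions were mapped in isolated mouse cardiomyocytes after Sham surgery and after 1 week of pressure overload (TAC), with 1 MeDIP-seq library per group. The Sham library had 12585289 tags, of which 29.9% lay in peaks, and the TAC library 14658177 tags, of which 34.7% lay in peaks, per the file headers. The authors' lists hold 135886 Sham peaks of 653 bp on average and 162107 TAC peaks of 634 bp on average. They cover 88.8 Mb in Sham and 103 Mb in TAC. A peak marks a region where methylated DNA was enriched over input, and it is not a methylation level. All differences below are between 2 libraries and have no replicate check.

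The comparison of Sham with TAC asks where in the genome 5mC enrichment differed between the isolates of cardiomyocytes after 1 week of pressure overload. Most Sham peaks had a TAC counterpart, and TAC carried a larger set of peaks of its own. Of the Sham peaks, 66.1% (95% interval 65.9 to 66.4) overlapped a TAC peak, and of the TAC peaks 55.6% (55.3 to 55.8) overlapped a Sham peak. After shifting the lists along their chromosomes the shares were 8.22% and 6.91% on average, and after shifts of 20 to 200 kb they were 10.97% and 9.17%. There were 71997 TAC-only and 46025 Sham-only peaks, a ratio of 1.56 (1.55 to 1.58).

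Sharing followed peak strength. In the first 10% of each list by order, where the median inferred tag number was 75 in Sham and 85 in TAC, 98.4% of peaks were shared in both libraries. In the last 10% the shares were 39.5% for Sham and 22.7% for TAC. The widest peak of both lists lay within Dmd, the dystrophin gene, on chromosome X (83583328 to 83603429 in Sham, 20102 bp, and 83583319 to 83603891 in TAC, 20573 bp). A peak within Zfp777 on chromosome 6 (11942 bp in Sham, 10987 bp in TAC) and one 697 kb from Cdh10 on chromosome 15 (9958 and 10531 bp) were also shared.

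The size of the TAC excess varied with the threshold. The ratio of TAC to Sham peaks was 1.19, close to the ratio of total tags, 1.16. With both lists held to a nearly equal depth-scaled threshold (at least 11 inferred tags in Sham and 13 in TAC, or 8.74 and 8.87 per 10000000, the TAC value being the stricter), it was 1.09, and the ratio of TAC-only to Sham-only peaks was 1.24. With at least 20 inferred tags per 10000000 in both, these ratios were 1.19 and 1.67. With TAC reduced to the Sham number of peaks at random, the ratio of TAC-only to Sham-only peaks was 0.998, and by order it was 0.962 at a peak ratio of 0.987.

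**Figure D1:**
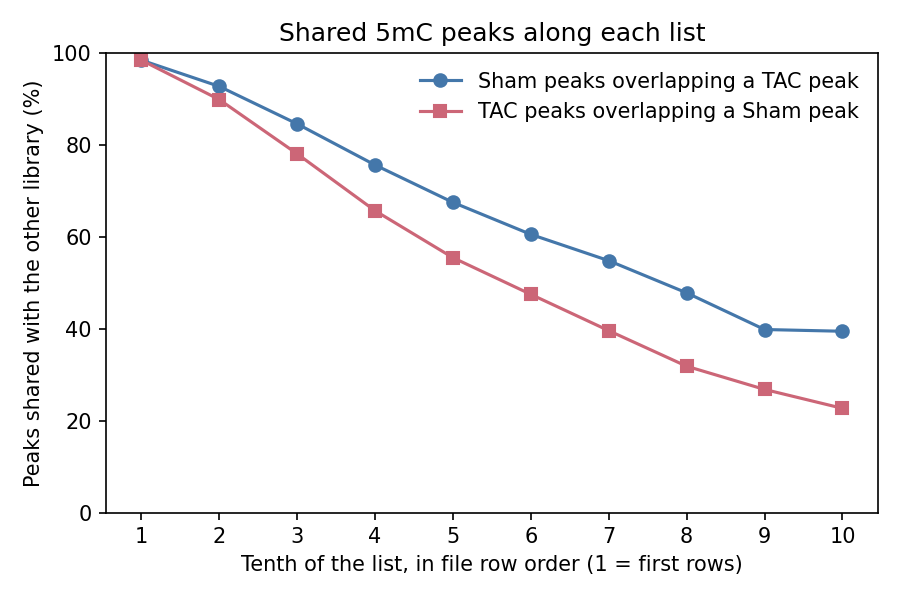
Percent of peaks that overlap a peak of the other library (y axis), in steps of 10% of each list in its file order (x axis, 1 is the first step), for Sham (circles) and TAC (squares). Both lines start at 98.4% and end at 39.5% for Sham and 22.7% for TAC.

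TAC peaks lay outside genes more often than Sham peaks. In TAC 51.1% (50.8 to 51.3) of peaks had their midpoint in an annotated gene, against 56.2% (55.9 to 56.5) in Sham, while genes cover 45.7% of the chromosomes' length. Peaks outside genes numbered 79337 in TAC and 59537 in Sham, a ratio of 1.33 (1.32 to 1.35), and peaks in protein-coding genes 67988 and 63482, a ratio of 1.07 (1.06 to 1.08). Of TAC-only peaks 46.4% were in genes, against 59.0% of Sham-only peaks. Shared peaks lie at the same positions in both lists, so their shares are nearly equal by construction (54.8% in TAC and 54.7% in Sham). Peaks in long non-coding RNA genes alone had a ratio of 1.14 (1.11 to 1.17).

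The ratio was graded by gene density. Autosomal 1 Mb windows without a protein-coding gene held 7112 Sham and 12441 TAC peaks, a ratio of 1.75 (1.70 to 1.80). Windows with 1 to 2 genes had a ratio of 1.40, windows with 3 to 5 genes 1.20, with 6 to 10 genes 1.11, with 11 to 20 genes 1.05 and with 21 or more genes 1.07 (1.05 to 1.10). On 19 of 19 autosomes the ratio was higher in windows with at most 2 genes (1.30 to 1.61) than in windows with more than 10 genes (0.973 to 1.16). Among autosomes the ratio ran from 1.12 on chromosome 19 to 1.27 on chromosome 16. Chromosome X, present as 1 copy in male cells, held 1537 Sham and 2679 TAC peaks, a ratio of 1.74 (1.64 to 1.86), and chromosome Y held 55 and 124. Peaks were sparse on chromosome X, with 9.01 Sham peaks per Mb against 54.6 on autosomes. The ratio on chromosome X was lower under each filter on the inferred tag number, as given below. At a nearly equal depth-scaled threshold the ratio in windows with more than 20 genes was 0.984, with an interval that holds 1 (0.963 to 1.01), and in windows without a gene 1.56 (1.52 to 1.61).

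**Figure D2:**
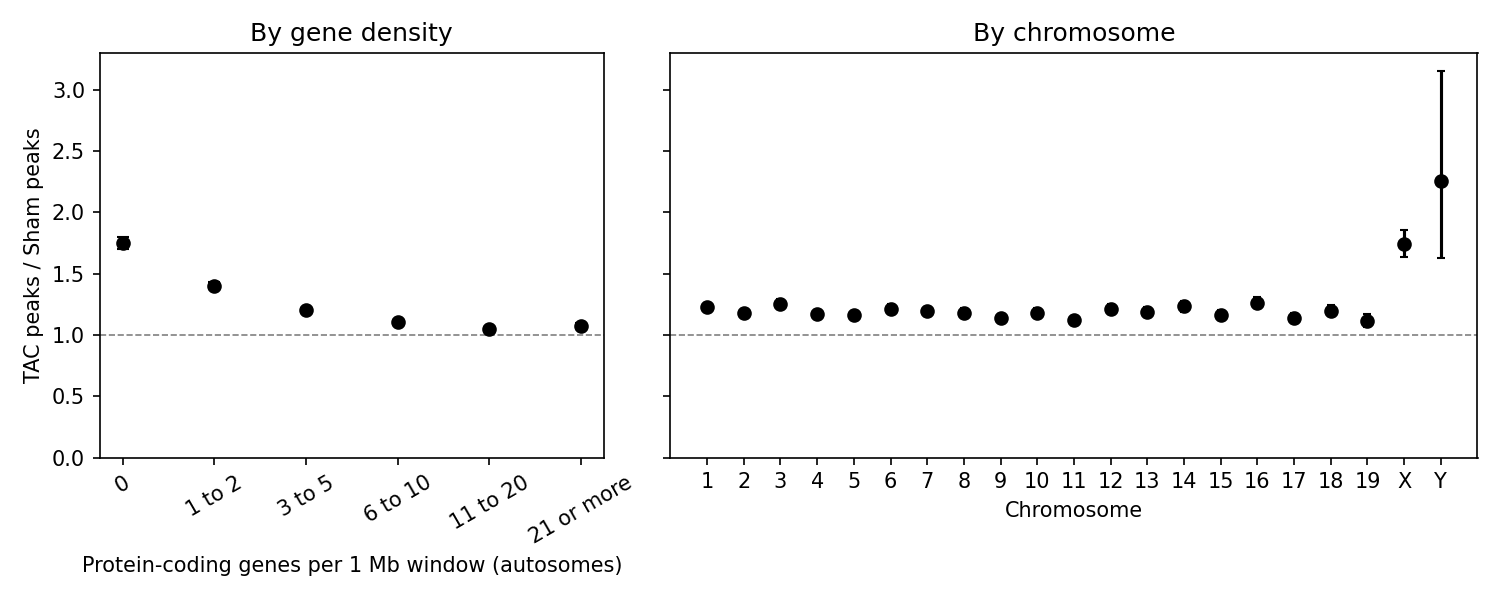
Ratio of TAC to Sham peak numbers (y axis, dashed line at 1) by protein-coding genes per autosomal 1 Mb window (left) and by chromosome (right). Points are ratios and bars their 95% counting intervals. Windows without a gene (1.75) and chromosomes X (1.74) and Y (2.25) lie above the autosomes, which run from 1.12 to 1.27.

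The 12 genes with the highest lower bound of the TAC share of peaks held 145 Sham and 428 TAC peaks together. Dlg2, a synaptic scaffold gene on chromosome 7 (90476188 to 92449246), held 36 Sham and 90 TAC peaks, a TAC share of 71.4% (62.7 to 79.1). Grm5, a metabotropic glutamate receptor gene on the same chromosome (87583981 to 88135063), held 8 and 31, and Dgkb, a diacylglycerol kinase gene on chromosome 12 (37880169 to 38634239), also held 8 and 31. Cntn4, encoding a contactin, held 14 and 43, Csmd3 15 and 42, Lrp1b, of the LDL receptor family, 36 and 79, and Thsd7b 20 and 49. Abca16 held 1 and 12, Bicd1 1 and 11, and Dnah9, an axonemal dynein gene, 6 and 24. Ttbk2 and Mipol1, which overlaps another protein-coding gene, each held 0 and 8. Their pooled ratio was 2.95 (2.44 to 3.59) and their median length 653 kb, and a high lower bound needs many peaks, which favours long genes. The 500 kb on either side of them held 412 Sham and 606 TAC peaks, a ratio of 1.47 (1.30 to 1.67).

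The 12 genes with the lowest upper bound of the TAC share held 405 Sham and 227 TAC peaks together. Smyd3, a lysine methyltransferase gene on chromosome 1 (178951960 to 179518053), held 101 Sham and 76 TAC peaks, with 37 Sham-only and 10 TAC-only peaks. Dock9, encoding a guanine nucleotide exchange factor, on chromosome 14 (121538365 to 121797900), held 55 and 32, with 25 Sham-only and 0 TAC-only peaks. Glis1 held 41 and 23, Plcb4, a phospholipase C gene, 38 and 24, Ldlrad3 35 and 18, Plekha7 30 and 15, Ralgps1 23 and 9, and Spire1, an actin nucleator gene, 22 and 8. Fbln1, encoding the matrix protein fibulin, held 20 and 8, Crim1 20 and 9, Cbx7, a Polycomb gene, 11 and 3, and Kif27 9 and 2. Some intervals of the TAC share spanned an even split. They were those of Smyd3 (35.5% to 50.6%), Cbx7 (4.66% to 50.8%), Crim1 (15.3% to 50.8%), Kif27 (2.28% to 51.8%) and Plcb4 (26.6% to 51.9%). Ralgps1, Glis1, Cbx7 and Crim1 each overlap another protein-coding gene. Their pooled ratio was 0.560 (0.474 to 0.661), and the 500 kb on either side held 998 and 1037 peaks. All 24 genes were picked for their difference, so pooled ratios overstate it, and a gap between genes and flanks is built into the choice of both sets. Over protein-coding genes with any peak, 11068 of 14033 had peaks in both libraries, 1301 in Sham alone and 1664 in TAC alone.

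**Figure D3:**
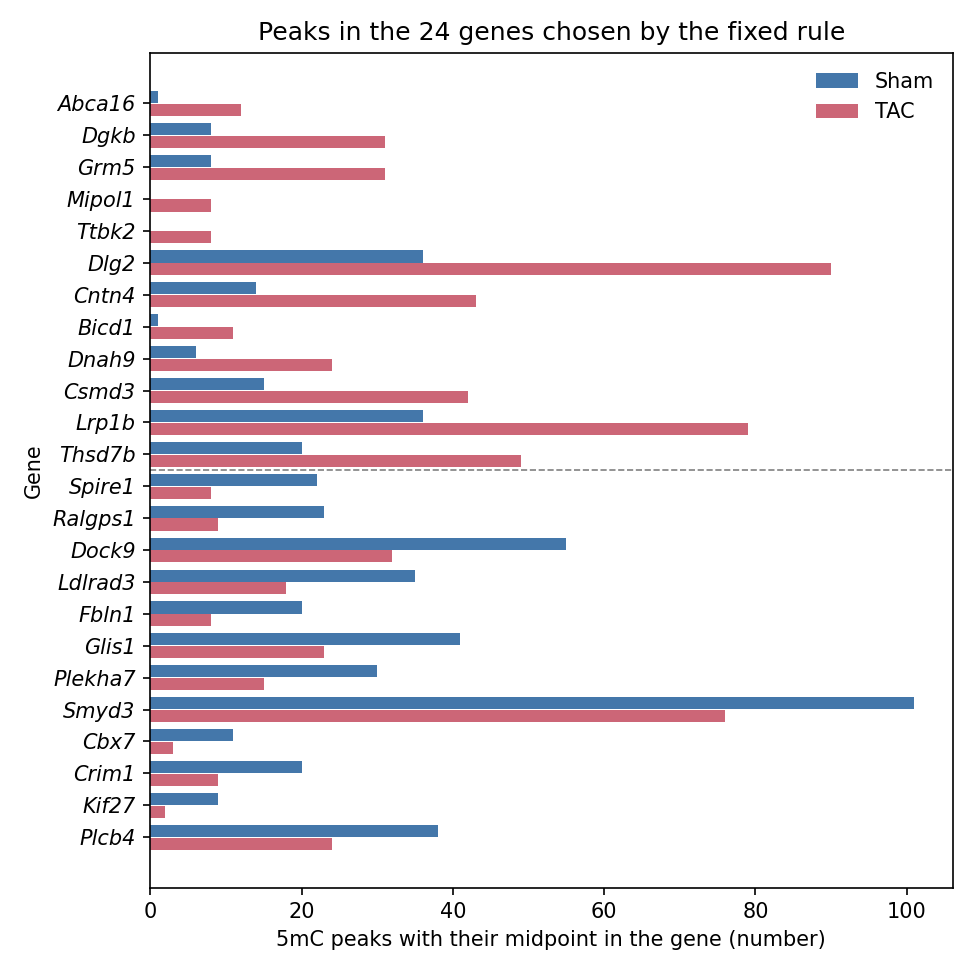
Number of 5mC peaks with their midpoint in each gene (x axis) for Sham and TAC, for the 12 genes with the highest lower bound of the TAC share (above the dashed line) and the 12 with the lowest upper bound (below it). Bars are counts from 1 library each. Dlg2 had 36 and 90 peaks, and Smyd3 101 and 76.

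The natriuretic peptide genes Nppa and Nppb, the skeletal actin gene Acta1 and the calcium pump gene Atp2a2 held no peak in either library. Myh6 and Myh7, which encode the cardiac myosin heavy chains and lie side by side on chromosome 14, held 3 and 5, and 4 and 5, Sham and TAC peaks. All 3 Sham peaks of Myh6 and all 4 of Myh7 were shared. Myh6 overlaps another protein-coding gene. Ryr2, the calcium release channel gene, held 20 and 31 peaks, with 4 Sham-only and 15 TAC-only, and a TAC share of 60.8% (46.1 to 74.2). Ttn, the titin gene, held 5 and 9. Among genes that write or erase 5mC, Dnmt3a held 7 and 5, Tet1 7 and 9, Tet2 4 and 4, and Tet3 4 and 5, and Dnmt3b held 2 and 2, none of them shared. Each interval of the share of all peaks spans an even split. Of unshared peaks alone, the TAC share in Ryr2 was 78.9% (54.4 to 93.9), an interval that holds the 66.2% of genes in windows of like gene density, and the intervals of the other genes of this group with unshared peaks spanned an even split. Peak numbers do not give the signal within shared peaks. Those of Dnmt3a had 11, 14, 29 and 21 inferred tags in Sham and 22, 26, 103 and 29 in TAC. These tag numbers are not scaled for depth. In Ryr2, Ttn, Tet1 and Tet2 some shared peaks had fewer inferred tags in TAC, such as 55 in Sham and 28 in TAC within Tet1.

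With gene bodies as annotated, none of the 19 lists lay outside the central 95% of random lists, where 0.95 would at the nominal rate. Of 100 simulated lists of unchanged genes, 100 or 98 lay within it, depending on the pool. Fewer than 0.95 are thus to be expected, and finding none says little. The ratio over all genes from which lists were drawn was 1.08. The 30 sarcomere and Z-disc genes held 86 Sham and 107 TAC peaks (ratio 1.24, percentile 89.0), with more TAC peaks in 13 and fewer in 4. Nebl held 18 and 23. Calcium handling genes held 227 and 263 (1.16, percentile 77.3), with 9 members higher in TAC, such as Slc8a1, the sodium-calcium exchanger gene (11 and 22), and Trdn, encoding triadin (3 and 13), and 3 lower, such as Stim1 (55 and 44). Cardiac transcription factors held 133 and 166 (1.25, percentile 89.7), among them Esrrg (47 and 61) and Meis1 (2 and 7). Fetal and load-induced genes held 44 and 39 (0.886, percentile 9.39), and with 5000 bp added to gene bodies they held 66 and 55 and lay below the range of random lists (0.833, percentile 1.38). Hypertrophic signalling genes held 388 and 435 (1.12, percentile 71.7). Ion channel and gap junction genes held 206 and 198 (0.961, percentile 13.4), with the pacemaker channel gene Hcn4 at 8 and 4. Random lists matched also on gene density moved these percentiles. They were then 95.4 for sarcomere and Z-disc genes, 62.6 for calcium handling genes and 68.0 for cardiac transcription factors. For fetal and load-induced, hypertrophic signalling, and ion channel and gap junction genes they were 15.975, 62.47 and 20.25.

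Among metabolic genes, fatty acid oxidation genes held 111 and 127 (1.14, percentile 68.4), with 8 members higher and 8 lower in TAC. Ppargc1a, a coactivator of mitochondrial genes, held 43 and 53, and Cd36, the fatty acid transporter gene, 0 and 5. The acetyl-CoA carboxylase genes Acaca and Acacb held 23 and 19, and 14 and 12. Glucose use genes held 39 and 42 (1.08, percentile 51.9). The 34 oxidative phosphorylation genes held 7 and 14 (2.0, percentile 95.8), with 26 of them free of peaks in both libraries. DNA methylation machinery held 56 and 61 (1.09, percentile 56.0).

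Markers of other heart cell types, which an isolate of cardiomyocytes could hold, went both ways. Whether the Sham and TAC isolates differed in their content of such cells was not tested. Fibroblast and matrix markers held 148 Sham and 133 TAC peaks (0.899, percentile 3.16), with 12 members lower in TAC, such as Col6a1 (5 and 0) and Col5a1 (27 and 21), and 8 higher, such as Dcn (2 and 6). Endothelial markers held 157 and 143 (0.911, percentile 5.34), with Cdh5, the VE-cadherin gene, at 6 and 2. Smooth muscle and pericyte markers held 97 and 96 (0.990, percentile 26.8), and immune cell markers 51 and 64 (1.25, percentile 85.2). Matched also on gene density, the fibroblast and matrix list fell below the range, at percentile 2.40, and the immune cell list moved to percentile 95.9. Imprinted genes held 118 and 110 (0.932, percentile 6.70), although Snrpn held 6 and 14. Germline genes held 76 and 78 (1.03, percentile 33.1), housekeeping genes 16 and 16 (1.00, percentile 33.9), cell cycle genes 73 and 67 (0.918, percentile 10.4), and developmental homeobox and Polycomb target genes 53 and 56 (1.06, percentile 46.2).

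**Figure D4:**
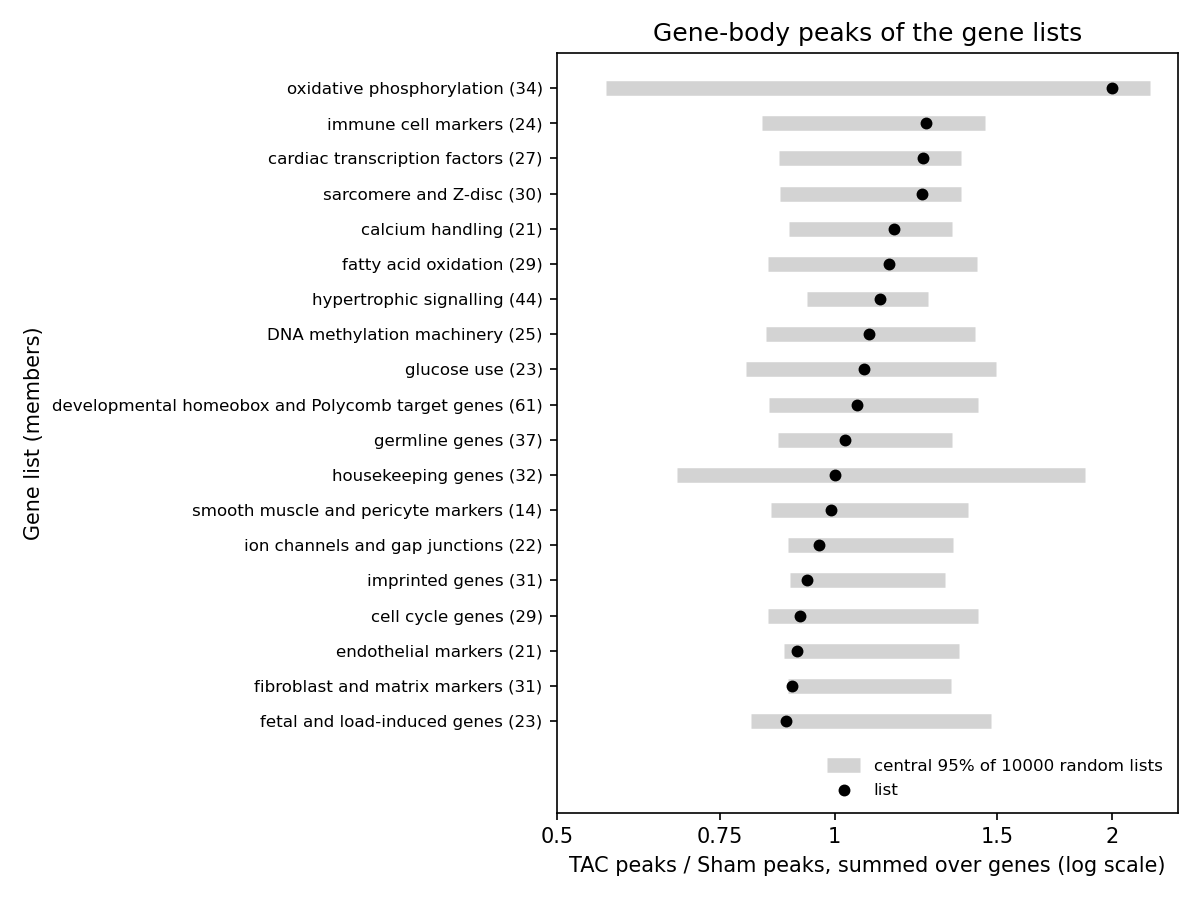
Ratio of TAC to Sham peaks summed over the genes of each list (x axis, log scale) for 19 gene lists with their member numbers (y axis). Points are the lists and grey bars the central 95% of 10000 random lists matched on peak number. All 19 points lie within their bars.

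Most genes of the germline and imprinted lists were covered at an end in both libraries. The germline list has 37 genes, many of which are silenced by methylation in somatic tissues. Of these 37, 31 (83.8%) were covered at an end in Sham and 27 (73.0%) in TAC, among them Dazl, Ddx4, Mael and Sycp1 in both. Asz1, Dpep3, Dpp4, Fkbp6, Rpl10l and Tex19.1 were covered in Sham alone, and Nobox and Syce1 in TAC alone. Coverage in 1 library alone thus also occurred in this list. Of 31 imprinted genes 22 (71.0%) were covered in each library, including H19, Igf2r, Kcnq1ot1, Mest and Peg3 in both. Of 32 housekeeping genes 4 (12.5%) were covered in each. Immune cell genes were covered in 14 of 24 in Sham and 13 in TAC, at percentiles 99.9 and 99.1 of random lists. Over all protein-coding genes the shares were 23.6% in Sham and 24.5% in TAC.

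Some cardiac genes were covered at an end in 1 library. Of the sarcomere list, Flnc, Mybpc3, Myh7b, Nebl and Nexn were covered in TAC alone, and Myl4, Myom2 and Tnni1 in Sham alone. Actn2, Myh6, Myl3, Myl7, Tcap, Tnni3 and Tnnt2 were covered in both. Of the transcription factors, Gata6, Hand2, Meis1, Prox1, Tbx2, Tbx5 and Zfpm2 were covered in TAC alone, and Mef2c and Tbx18 in Sham alone, so that 6 of 27 were covered in Sham and 11 in TAC (percentiles 26.7 and 90.0 of random lists). Of fetal and load-induced genes 9 of 23 were covered in Sham and 4 in TAC (percentiles 85.6 and 9.50). The difference between these lists was not tested. Besides Myl4 and Tnni1, the genes Hmox1, Myc, Rcan1 and Tnfrsf12a were covered in Sham alone, and Egr1 in TAC alone. Of calcium handling genes, Cacna1c and Sri were covered in TAC alone and Casq2 in Sham alone. Dnmt1, Gadd45b and Tet3 were covered in TAC alone, Mbd3 in Sham alone and Tet2 in both.

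Across the genome, 1881 genes were covered at an end in TAC alone, 1680 in Sham alone and 3491 in both. The order turned at a nearly equal depth-scaled threshold (1580 in TAC alone and 1777 in Sham alone), with at least 20 tags per 10000000 (664 and 773), and with TAC peaks reduced to about the Sham number at random (1611 and 2137) or by order (1384 and 1934). The widest peaks at such ends were at Chd3 (2949 bp), Podn (2662 bp), Olfr769, Fam222a, Lhfpl4, Gm10318, Hpx, Cpa4, Axl and Casz1 in TAC. In Sham they were at Zfp777 (11942 bp), Jag2 (4148 bp), Zfp872, Fzd7, Rngtt, Anks6, Bop1, Otx1, Pnmal1 and Efhd2. Bop1 and Gm10318 overlap other protein-coding genes. Of these peaks, 8 of 10 in TAC and 10 of 10 in Sham overlapped a peak of the other library. That peak did not reach the 1000 bp on either side of a gene end, so these differ in extent. The difference can be small. At Zfp777, whose annotated start is 48017660, the Sham peak began at 48018283 and the TAC peak at 48018673. The peaks at Hpx and Cpa4 overlapped no Sham peak.

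**Figure D5:**
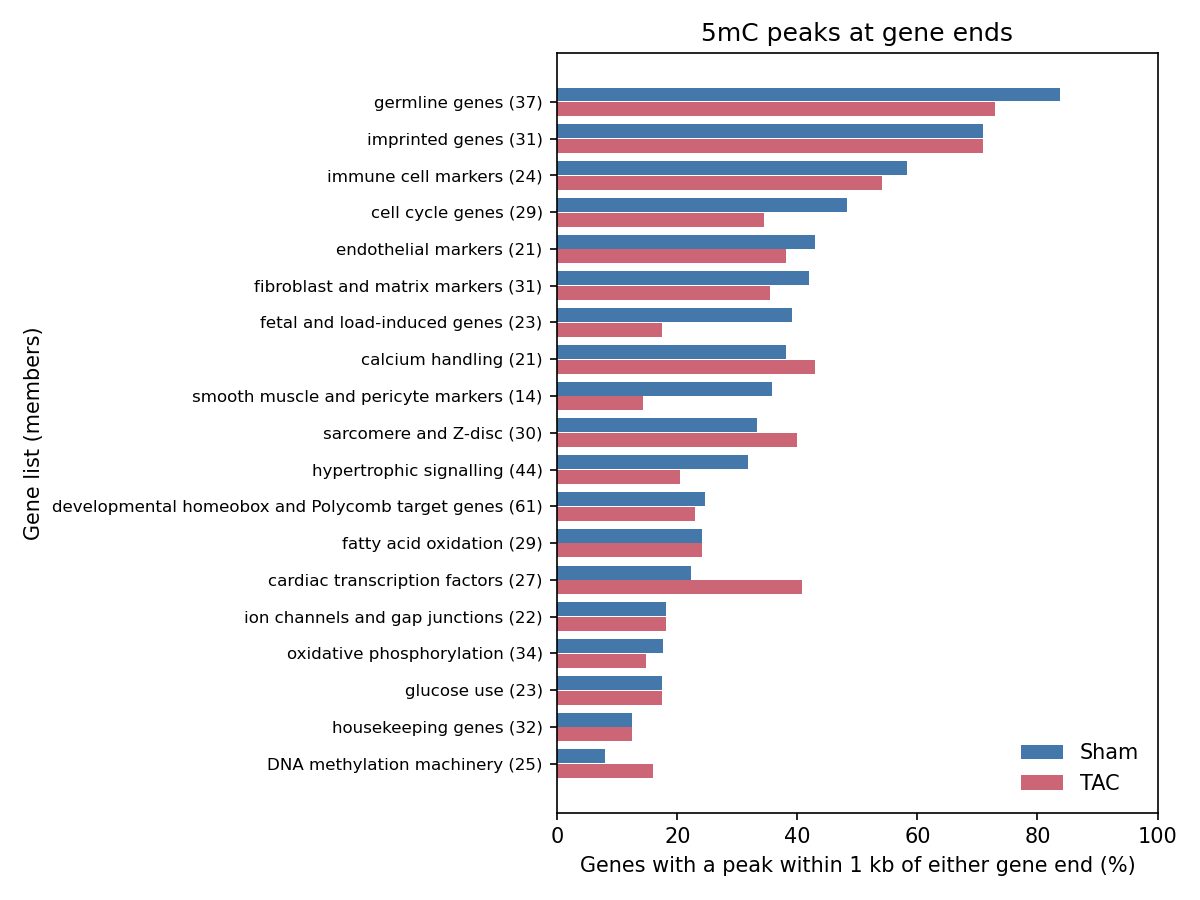
Percent of genes with a peak within 1 kb of either gene end (x axis) in Sham and TAC for 19 gene lists with their member numbers (y axis). Germline genes (83.8% and 73.0%) and imprinted genes (71.0% in both) have the longest bars, and housekeeping genes stand at 12.5% in both.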

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

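Filters on the inferred tag number, other window sizes and matching on gene density were chosen after seeing the data, and the other settings before. Under all settings run, the ratio of TAC to Sham peaks stayed above 1 in autosomal windows without a gene and on chromosome X, although with at least 20 tags per 10000000 the interval of chromosome X (1.10 to 1.51) held the ratio of all peaks, and a smaller share of TAC than of Sham peaks lay in genes. The ratio of TAC-only to Sham-only peaks and the ratio in windows with more than 20 genes did not keep their side of 1, and neither did the order of genes covered at an end in TAC alone and in Sham alone, which was 1611 against 2137 after a random draw, 1580 against 1777 at a nearly equal depth-scaled threshold and 1384 against 1934 with an equal number by order. Removing TAC peaks lowers those ratios by construction, and the cause of the other shifts was not tested. With overlap of at least 50% of both peaks, 50.3% of TAC and 59.97% of Sham peaks were shared, and the ratio of TAC-only to Sham-only peaks was 1.48. With peaks within 500 bp counted as shared these were 56.8%, 67.6% and 1.59, and on autosomes alone the TAC share was 55.9% and the ratio 1.54. A random draw of TAC peaks to the Sham number, which sets the peak ratio to 1, gave 55.4% of Sham peaks shared, a TAC-only to Sham-only ratio of 0.998, ratios of 1.46 in windows without a gene, 0.899 in windows with more than 20 genes and 1.46 on chromosome X, and 1 gene list (fibroblast and matrix) outside the random range. By bases in place of midpoints, 57.4% of Sham and 51.8% of TAC peak sequence lay in genes. With 5000 bp added to gene bodies, 1 list (fetal and load-induced) lay outside. At a nearly equal depth-scaled threshold the peak ratio was 1.09, the shared shares 59.0% (TAC) and 64.0% (Sham), the TAC-only to Sham-only ratio 1.24, the ratios 1.56 without a gene, 0.984 with more than 20 genes and 1.42 on chromosome X, and 1 list (fibroblast and matrix) lay outside. Cutting each list near its middle by order kept 65602 Sham peaks (48.3%) and 82364 TAC peaks (50.8%), since tied peaks stay together. The cuts lay at 15.1 and 14.3 tags per 10000000. Against 1.19 in the full lists, the peak ratio was 1.26 after this uneven cut, which raises it. There the shared shares of TAC and Sham and the ratio of TAC-only to Sham-only peaks were 57.3%, 71.6% and 1.89, with 58.8% of Sham and 52.4% of TAC peaks in genes, 1082 genes covered at an end in TAC alone and 994 in Sham alone, ratios of 2.20 without a gene and 1.47 on chromosome X, and 2.02 for the no-gene ratio over the gene-rich ratio, which was 1.63 as reported. With an equal number of peaks by order (peak ratio 0.987) they were 62.2%, 61.3% and 0.962, with 51.4% of TAC peaks in genes, ratios of 1.39 without a gene, 0.902 with more than 20 genes and 1.17 on chromosome X, 1.54 for the ratio of ratios, and 1 list (cell cycle) outside. With at least 20 tags per 10000000 (42597 Sham and 50844 TAC peaks, ratio 1.19) they were 60.3%, 71.7% and 1.67, with 59.8% and 53.4% in genes, 664 and 773 genes covered in TAC and in Sham alone, ratios of 2.05, 1.04 and 1.29, 1.98 for the ratio of ratios, and 2 lists (imprinted and germline) outside. Windows of 500 kb gave 1.59 without a gene and 1.49 for the ratio of ratios, and windows of 2 Mb gave 1.93 and 1.82. Matching on gene density put 1 list (fibroblast and matrix) outside. The stricter threshold by score was not run because the score is the same for every peak, and the CpG island settings were not run. No paired analysis was possible because each group has 1 library. Counting error is wide for genes with few peaks, as for Myh7, where 4 Sham and 5 TAC peaks gave an interval of the TAC share from 21.2% to 86.3%.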

Other observations

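Gene families were looked at after the data were examined, 16 in all, each set among random lists matched on peak number and gene density. The random lists drew each gene independently from anywhere in the genome. Where members of a family lie side by side and share a regional ratio, the percentiles below may be too extreme. Clustering of members was not taken into account. GABA-A receptor genes, which encode inhibitory ion channel subunits, held 63 Sham and 126 TAC peaks (ratio 2.0, percentile 99.98). Of the 126 TAC peaks 40 lay in Gabrg3, 23 of them TAC-only, and the ratio without Gabrg3 was not computed. Metabotropic glutamate receptor genes held 92 and 154 (1.67, percentile 98.6). Of these peaks 8 Sham and 31 TAC lay in Grm5, a gene already picked above for its high TAC share. The ratio without Grm5 was not computed, so the position of this family may rest on that gene. Cytochrome P450 genes held 135 and 178 (1.32, percentile 99.8). Vomeronasal Vmn2r genes held 42 and 79 (1.88, percentile 100). For these 4 families the ratio stayed above 1 under 4 filters on the inferred tag number, under which the ratio of all peaks ran from 0.987 to 1.26. The strictest filter left 42597 Sham and 50844 TAC peaks, a ratio of 1.19. There metabotropic glutamate receptor genes held 25 and 30 (1.20), so their ratio was close to that of all peaks. Under that filter GABA-A receptor genes held 11 and 21 (1.91), cytochrome P450 genes 35 and 57 (1.63), and Vmn2r genes only 3 and 12. Hox genes held 17 and 9 (0.529, percentile 0.745) and reached 1.00 under 1 filter that left 1 peak in each library. Dock genes held 238 and 211 (0.887, percentile 2.08), and their ratio was 1.04 at its highest under the filters. Of these peaks 55 Sham and 32 TAC lay in Dock9, a gene already picked above for its low TAC share. The ratio without Dock9 was not computed, so the low percentile may rest on that gene. Solute carrier genes held 1470 and 1548 (1.05, percentile 58.7), and zinc finger genes 763 and 817 (1.07, percentile 54.1). Of 1110 olfactory receptor genes 92.2% had no peak in either library, against 35.9% of all protein-coding genes.

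The tests of the 3 patterns below were chosen after the results were seen, except the simulated spread of peaks over genes, whose bound was written before its result. The TAC excess in gene-poor windows was weighed first. The lower depth-scaled threshold of TAC does not by itself account for it. At a nearly equal depth-scaled threshold the no-gene ratio was still 1.59 (1.53 to 1.65) times the gene-rich ratio. That threshold scales by total tags and leaves the shares of tags in peaks unequal, 29.9% in Sham and 34.7% in TAC. Whether this difference gives the trend was not tested. In both lists weak peaks lay in windows without a gene more often than strong ones. From the first to the last 10% of the list, the share of autosomal peaks there rose from 2.71% to 7.20% in Sham. In TAC it rose from 3.77% to 9.38%, and it was above Sham at both ends. A few regions do not account for the TAC excess in gene-poor windows either, with the same direction on 19 of 19 autosomes. A preference of either library for a base composition may give the same graded trend, as in windows with 1 to 2 genes (1.40), and it cannot be told apart from pressure overload because each group has 1 library and no sequence was used. Pressure overload stays open and untested.

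For strong peaks present in 1 list, weighed next, of 69360 TAC peaks with at least 24 inferred tags, 2 times the threshold, 11774 lay more than 1000 bp from any Sham peak, and of 54083 Sham peaks with at least 22 tags 5498 lay as far from a TAC peak. With the inferred tag numbers, counting error was estimated to give 523 such TAC peaks and 184 such Sham peaks, with the tags expected in the other library shrunk for the choice of strong peaks. This estimate replaced one without shrinking, which gave 66.5 and 5.89, after that had been seen. The filters against input and clonal tags removed 2249 putative Sham peaks in all. That is too few for the 11774, and for the 2790 TAC peaks with at least 36 tags. The same filters removed 2507 putative TAC peaks. This is too few for the 5498 Sham peaks but more than the 1271 Sham peaks with at least 33 tags. Putative peaks outnumbered listed peaks (367581 against 162107 in TAC), so the units are unlike. Whether the filters account for the 1271 therefore cannot be told. Some of the strongest unshared peaks of both lists lay at 1 locus. Within Sfi1 on chromosome 11, Sham-only peaks had 350, 338 and 337 inferred tags and a TAC-only peak had 227. Whether artefacts of such loci give strong unshared peaks was not tested. Variation between libraries and pressure overload also stay open, since no library was repeated.

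For genes with more Sham than TAC peaks, weighed last, if list-only peaks were spread over genes at random within gene-density classes, 25 to 56 of 11722 genes would lie below their class in 200 simulations, and 148 did. Above their class lay 93 genes, against 15 to 42, so the excess ran in both directions. The simulation places peaks independently, so clusters of neighbouring peaks may account for part of that excess. For the 12 named genes a regional trend stays open, because they were chosen on the value within them, so a flank ratio of 1.04 (0.952 to 1.13) above their own excludes nothing. A hypothesis that these gene bodies lost 5mC enrichment after pressure overload stays untested with 1 library per group.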
